A study of Mus musculus with 73 samples.

How the data were processed

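Polyadenylated RNA of 73 mouse mammary tumours was sequenced from strand-marking libraries, 1 library per tumour, per the labels' protocols. The authors deposited 2 tables of the whole series. The first holds read counts per gene for 39438 gene symbols, and the deposited log2 table holds log2 normalized counts for 37148 symbols, of which 36113 occur in both. The submitters' processing notes name cutadapt 2.10, STAR 2.7.3a, featureCounts 2.0.0, DESeq and the mouse genome build mm10, without order or settings. Whether the authors counted reads by strand is not given in the sources used here. In every library 100% of the deposited log2 values, after removal of a library factor and of 1 added count, were whole numbers within 0.01 count, so they are the counts of the log2 table divided by 1 factor per library. The count table held 24 symbols that spreadsheet software had turned into dates, with 0.1688% of all counts. Those symbols were left as they were. DNA copy-number data of the series were not analysed here.

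Groups were taken from the genotype and histology labels: adenocarcinomas, carcinosarcomas and sarcomatoid tumours with Brca1 L1363P, adenocarcinomas and carcinosarcomas of the KP model, and adenocarcinomas of the KB1P and KB2P models. KB1P tumours carry 2 kinds of title, KB1P and KB1PM, which were fitted as 2 groups and averaged with equal weight for the comparisons of KB1P. The first field of each library description was read as a sequencing run. All 29 L1363P and KP libraries belong to run 5625. The KB1P libraries belong to runs 1857, 2119 and 3528, the KB1PM libraries to runs 1725 and 1756, and the KB2P libraries to runs 2459, 2749 and 2802. Genotype and run can therefore not be separated where L1363P or KP tumours are compared with KB1P or KB2P tumours. The labels do not say that the tumours come from separate animals, so p-values measure only the spread between these samples. Tumours 54.1 and 54.2 share a number.

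Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr at a minimum count of 10, libraries were scaled with trimmed means of M values (TMM), and groups were compared with the quasi-likelihood F test with Benjamini-Hochberg adjustment (BH) at 0.05. Comparisons within run 5625 used 1 fit of its 29 libraries in 5 groups. Comparisons with KB1P or KB2P used 1 fit of all 73 libraries in 8 groups, so their CPM (counts scaled to a common library size) differ slightly between the 2 fits. Levels of Brca1, Brca2, Trp53 and Palb2 over all 8 groups, and of single tumours across groups, were scaled over all genes of the 73 libraries. Within the 9 L1363P carcinosarcomas, the labelled percentage of epithelial tumour was fitted as a slope per 10 percentage points. The 12 KB2P libraries of run 2749 were compared with the 9 of run 2459 as a yardstick for the difference between these 2 runs, which need not hold for other runs. CPM values are given as mean and standard deviation (SD) over tumours, log2 fold changes with standard errors (SE). A fold against a group with no count is a lower bound, with the empty group set to 3 counts in all. Such floors cover counting error only. Principal components used log2 CPM with a prior count of 2 and the 2000 most variable genes. Gene positions are those of the mouse annotation for GRCm38, the assembly behind mm10.

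The groups, tests, gene lists and rules for naming genes were fixed before the data were examined. The 28 gene lists hold 311 members: epithelial, basal epithelial, luminal epithelial, milk protein, squamous differentiation, mesenchymal, fibroblast and collagen, smooth muscle and pericyte, endothelial, adipocyte, skeletal muscle, T and NK cell, B and plasma cell, macrophage, neutrophil, antigen presentation, interferon response, proliferation, homologous recombination, end joining and resection control, p53 target, hypoxia, oncogene, tumour suppressor, drug efflux, mitochondrially encoded, haemoglobin and ribosomal protein genes. Lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with BH adjustment over the lists, and again with an estimated correlation. Of all calls at the preset correlation, 2 held with the estimated one, both for the ribosomal protein list, in L1363P against KB1P and against KB2P adenocarcinomas. List scores are means over members of log2 CPM centred on the 29 libraries of run 5625. They were related to the epithelial percentage by exact permutation tests of Pearson and Spearman correlations, two-sided. Named genes are Brca1, Brca2, Trp53 and Palb2 in every comparison, then up to 10 genes per direction with the largest log2 fold changes among those with adjusted p under 0.05, an absolute log2 fold change of at least 1 and a mean log2 CPM of at least 1, leaving out Gm and Rik symbols, then up to 4 called members of each list described and members named for not passing. Met, Yap1 and their neighbours were examined across tumours after their values had been seen.

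Alternatives fixed beforehand were DESeq2 1.42.0 size factors, no count filter, the DESeq2 Wald test, limma on the deposited log2 values, fits of the compared groups only, an absolute log2 fold change of at least 1 as an added criterion, leaving out each tumour of the groups of 3 to 5, single runs, carcinosarcomas of at least 75% epithelium, leaving out tumour 54.2, and the tumour number as a block. Alternatives chosen after seeing the data were KB1P run 3528 alone or left out, leaving out 6 libraries with skeletal muscle genes, leaving out the 3 tumours of other groups nearest to the sarcomatoid mean, a correction for GC content per library, and leaving out ribosomal protein genes and pseudogenes. Every group comparison was repeated over 100 splits of its libraries, or all 56 where no more exist. Each edgeR comparison was tested on simulated data with 200 changed genes, drawn from genes with a mean log2 CPM of at least 1. The shares recovered do not cover genes below that level. For L1363P sarcomatoid tumours against adenocarcinomas, over 16108 genes, 29.9% of genes changed by a factor of 2 were recovered, 67.2% of those changed by a factor of 4 and 80.3% of those changed by a factor of 8. For KP carcinosarcomas against adenocarcinomas, over 16110 genes, the shares were 14.9%, 64.2% and 77.3%. In these 2 simulations 9 of 127 and 7 of 111 calls were genes that had not been changed. No recovered gene had the wrong direction in any of the simulated comparisons. Figures were drawn with matplotlib.

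Total counts ranged from 7325180 to 31615237 per tumour. Gene totals of Brca1, Brca2 and Trp53 add up reads from all exons, so they do not show whether some exons were deleted in a tumour. Ribosomal protein genes share sequence with many processed pseudogenes, and their counts are uncertain wherever the authors' counting could split them. Overlapping and antisense genes are uncertain for the same reason. Results for some genes are not reported here.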

Results

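RNA of 73 mouse mammary tumours was compared across 8 groups. The L1363P tumours, which carry the Brca1 variant p.L1363P, comprised 3 adenocarcinomas, 9 carcinosarcomas and 9 sarcomatoid tumours. KP tumours comprised 5 adenocarcinomas and 3 carcinosarcomas. The other adenocarcinomas were 11 titled KB1P, 10 titled KB1PM and 23 titled KB2P. In these established models p53 is lost alone (KP), or together with BRCA1 (KB1P) or BRCA2 (KB2P), in mammary epithelium. The genotype label of the L1363P tumours, KB1(L1363P)P, has the form of KB1P. Comparisons of L1363P with KP tumours are therefore not read as contrasts of p53. Total counts per tumour were 13103749 to 17550129 in the L1363P and KP groups and 7325180 to 31615237 in the KB1P, KB1PM and KB2P groups. The labels give adenocarcinomas as 100% epithelial, sarcomatoid tumours as 0%, L1363P carcinosarcomas as 2 to 98% and KP carcinosarcomas as 80 to 90%. They do not say that tumours come from separate animals, so p-values measure only the spread between samples.

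Brca1, which encodes the repair protein altered in the L1363P mice, reached 75.0 ± 17.7 CPM (mean ± SD) in L1363P adenocarcinomas (n = 3), 45.6 ± 11.8 in L1363P carcinosarcomas (n = 9) and 43.3 ± 10.0 in sarcomatoid tumours (n = 9). It reached 37.9 ± 17.6 CPM in KP adenocarcinomas (n = 5), 72.3 ± 15.8 in KP carcinosarcomas (n = 3), 32.7 ± 7.16 in KB1P (n = 11), 24.4 ± 6.21 in KB1PM (n = 10) and 58.3 ± 25.6 in KB2P tumours (n = 23). Brca2, a homologous recombination gene, ranged from 23.5 ± 10.0 CPM in KP adenocarcinomas to 56.1 ± 30.7 in KB1P tumours. Trp53, encoding p53, ranged from 20.6 ± 2.07 CPM in KP carcinosarcomas to 31.8 ± 15.7 in sarcomatoid tumours, where tumour 9.1 had 71.5 CPM. By median KB2P tumours were highest (30.1 CPM, against 27.7 in sarcomatoid tumours). Palb2, encoding the bridge between BRCA1 and BRCA2, ranged from 11.1 ± 3.42 CPM in KP adenocarcinomas to 17.5 ± 6.75 in KB1P tumours. Brca1 lies on chromosome 11 (101488764 to 101551955), Brca2 on 5 (150522630 to 150570329), Trp53 on 11 (69580359 to 69591873) and Palb2 on 7 (122107262 to 122132985). Gene totals do not show whether some exons were missing.

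**Figure D1:**
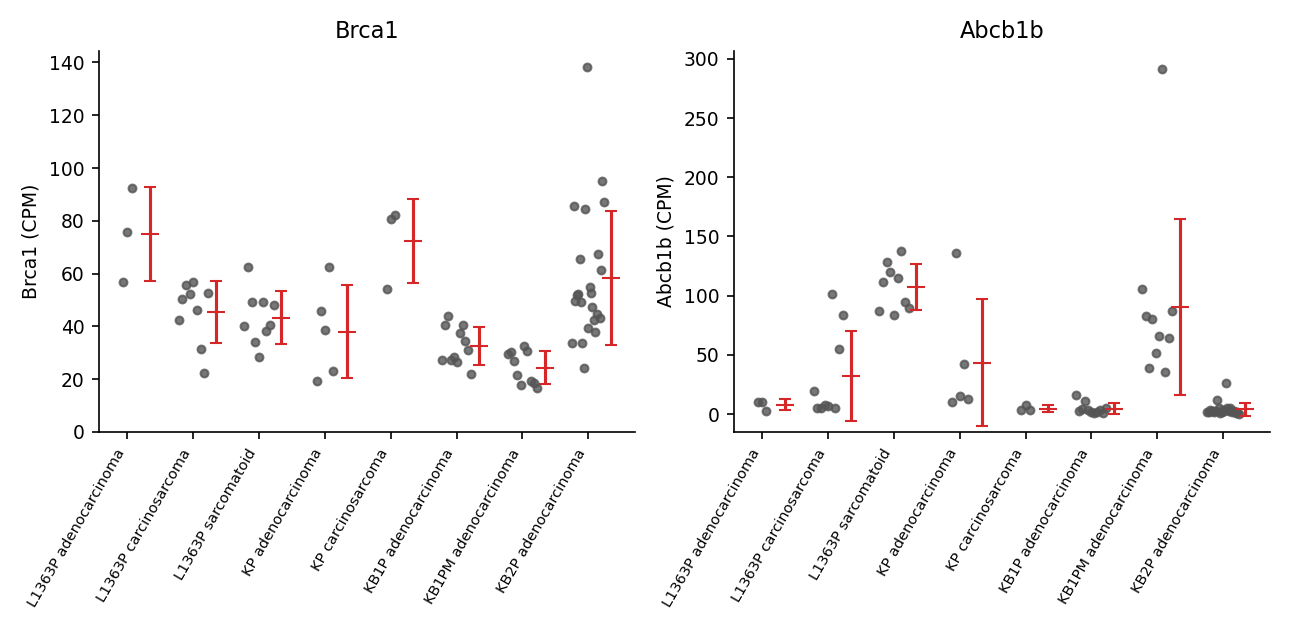
Brca1 and Abcb1b in CPM, each tumour a point, in the 8 groups (n = 3 to 23), with mean and SD in red. Abcb1b was high in the sarcomatoid and KB1PM groups and low in the KB1P and KB2P groups.

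Among the 29 L1363P and KP tumours the first principal component held 50.2% of the variance and the second 11.7%. On the first component all 9 sarcomatoid tumours lay together, joined by L1363P carcinosarcomas 17 (5% epithelial) and 4 (2%) and by KP adenocarcinoma 90.01A, which is labelled 100% epithelial. The mesenchymal gene score was higher in each of these tumours than in any other.

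**Figure D2:**
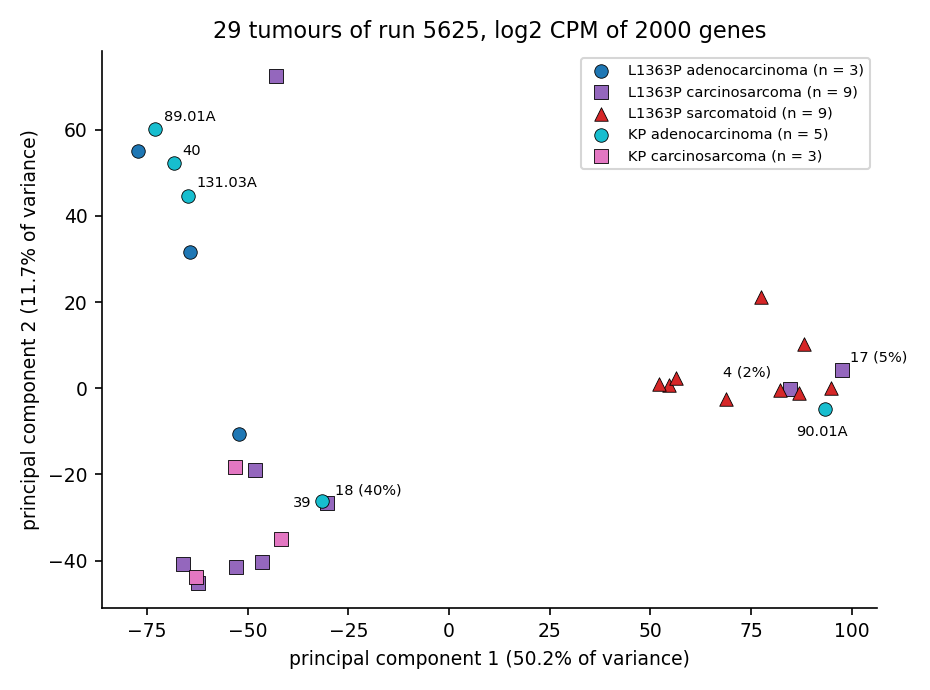
First and second principal components (50.2% and 11.7% of variance) of log2 CPM of 2000 genes in 29 tumours, coloured by group. The sarcomatoid tumours lie at the right with carcinosarcomas 17 and 4 and KP adenocarcinoma 90.01A.

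L1363P sarcomatoid tumours (n = 9) had less Brca1 than L1363P adenocarcinomas (n = 3), at 37.3 ± 8.54 against 68.0 ± 17.1 CPM (log2 fold change -0.87, SE 0.27, edgeR quasi-likelihood BH-adjusted p = 0.0192), with 2 of 3 adenocarcinomas above all sarcomatoid tumours. This call was lost without adenocarcinoma 26.2 or 52. Brca2 (-0.78, adjusted p = 0.0612), Palb2 (-0.56, adjusted p = 0.0991) and Trp53 (0.21, adjusted p = 0.578) did not pass the same edgeR quasi-likelihood test with BH adjustment, and 2 of 3 adenocarcinomas lay above all sarcomatoid tumours for Brca2 and for Palb2. Of 16147 genes tested, 1959 were higher and 2986 lower in sarcomatoid tumours, while limma on the deposited log2 values called 2450 higher and 2168 lower. The total of 4945 fell to 2490 without adenocarcinoma 26.2.

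Most epithelial genes were lower in the sarcomatoid tumours. Perp, a desmosome gene and p53 target, fell from 198.8 ± 34.0 to 4.10 ± 3.81 CPM (log2 fold change -5.60, SE 0.84, edgeR quasi-likelihood BH-adjusted p = 0.000119, 3 of 3 adenocarcinomas above all 9). Cldn3, a tight junction gene, fell from 89.7 ± 60.4 to 1.43 ± 1.89 CPM (-5.96, SE 1.02, edgeR quasi-likelihood BH-adjusted p = 0.00026, 3 of 3). Krt14, a basal keratin, fell from 601.8 ± 463.6 to 10.8 ± 8.31 CPM (-5.81, SE 0.95, edgeR quasi-likelihood BH-adjusted p = 0.000199, 3 of 3). Elf5, a luminal regulator, fell from 179.5 ± 123.7 to 2.93 ± 3.29 CPM (-5.93, SE 1.28, edgeR quasi-likelihood BH-adjusted p = 0.00157, 3 of 3). Gpx2, a glutathione peroxidase, had 0 counts in all 9 sarcomatoid tumours and 36.0 ± 17.5 CPM in adenocarcinomas, at least 1495-fold more. Snorc, a cartilage proteoglycan gene, had 3 counts in all sarcomatoid tumours against 38.8 ± 14.5 CPM. Erbb2, an epithelial growth factor receptor gene, fell from 144.8 ± 18.7 to 42.7 ± 17.0 CPM (-1.76, SE 0.40, edgeR quasi-likelihood BH-adjusted p = 0.00237, 3 of 3).

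Several mesenchymal, macrophage and efflux genes rose in the sarcomatoid tumours, but none of these sets passed camera with an estimated correlation. Twist1, a regulator of mesenchymal fate, rose from 4.35 ± 3.49 to 50.5 ± 12.3 CPM (log2 fold change 3.53, SE 0.60, edgeR quasi-likelihood BH-adjusted p = 0.00026, 9 of 9 above all 3). Fn1, encoding fibronectin, rose from 798.4 ± 473.9 to 16400 ± 8629 CPM (4.36, SE 0.96, edgeR quasi-likelihood BH-adjusted p = 0.00185, 9 of 9). Csf1r, the macrophage growth factor receptor gene, rose from 121.4 ± 54.8 to 620.3 ± 153.0 CPM (2.35, SE 0.58, edgeR quasi-likelihood BH-adjusted p = 0.00434, 9 of 9). Abcb1b, a drug efflux transporter gene, rose from 7.23 ± 3.98 to 92.6 ± 16.8 CPM (3.68, SE 1.03, edgeR quasi-likelihood BH-adjusted p = 0.00943, 9 of 9), and Abcb1a from 2.77 ± 1.60 to 29.1 ± 8.14 CPM (3.39, SE 0.81, BH-adjusted p = 0.0033, 9 of 9). Mmp1b, a matrix metalloproteinase gene, had 10.0 ± 7.90 CPM and 0 counts in the adenocarcinomas, at least 177.5-fold more. Mmp3, encoding stromelysin, rose from 21.2 ± 8.596 to 2847 ± 2391 CPM (7.07, SE 2.25, edgeR quasi-likelihood BH-adjusted p = 0.0198, 9 of 9), a call lost without any 1 of the 3 adenocarcinomas. Mmp1b and Mmp3 belong to the region around Yap1 described below. In the 12 tumours with Yap1 at 10 or more times its median they had median excesses of 20.3-fold and 14.8-fold. Bard1, encoding the BRCA1 partner, fell from 37.9 ± 12.6 to 13.0 ± 2.51 CPM (-1.54, SE 0.34, edgeR quasi-likelihood BH-adjusted p = 0.0019, 3 of 3).

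By list, 16 of 18 epithelial genes fell (16 adjusted over the list alone) and 11 of 12 basal (12 alone). So did 5 of 12 luminal (6 alone), among them Kit and Spdef, and 6 of 8 squamous genes (6 alone), among them Calml3 and Krt10. As sets they were lower by camera (BH-adjusted p = 7.26e-13, 8.37e-06, 0.00787 and 0.0398), but not with an estimated correlation (adjusted p = 0.33, 0.33, 0.394 and 0.394 with an estimated correlation). In the mesenchymal list 9 of 14 rose (12 alone), including Snai1 and Zeb2, and in the collagen list 12 of 15 (13 alone), including Fbn1, Col5a1 and Col3a1. The same held in the endothelial list for 7 of 10 (7 alone), including Cdh5 and Pecam1, and in the macrophage list 10 of 11 (10 alone), including Mrc1 and Lyz2. Camera placed these 4 sets higher (BH-adjusted p = 3.1e-07, 7.12e-07, 0.000365 and 1.92e-05; adjusted p = 0.33, 0.33, 0.394 and 0.394 with an estimated correlation). Neutrophil genes rose for 3 of 6 (6 alone), including Csf3r, and drug efflux genes for 4 of 5 (4 alone), including Abcc1 and Abcg2 (camera BH-adjusted p = 0.00955 and 0.00234; adjusted p = 0.429 and 0.33 with an estimated correlation). Of 16 interferon genes only Ifit2 rose, and 0 passed over the list alone (camera BH-adjusted p = 0.00787; adjusted p = 0.694 with an estimated correlation). Of 16 proliferation genes 7 fell (9 alone), including Cdk1, Mcm2 and Aurkb. Of 18 homologous recombination genes 5 fell (4 alone), including Xrcc2 (camera BH-adjusted p = 0.00237 for proliferation and 0.00787 here; adjusted p = 0.471 and 0.394 with an estimated correlation).

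The remaining lists were not shifted as sets at the preset correlation (camera BH-adjusted p in brackets). In the p53 target list 5 of 12 rose, including Mdm2, Ccng1 and Eda2r, and 2 fell, including Perp (camera BH-adjusted p = 0.212). In the oncogene list Mcl1 and Pik3ca rose and Erbb2 fell among 14 (0.212), while Yap1 reached 8092 ± 3611 against 288.5 CPM without passing (log2 fold change 4.81, SE 1.89, edgeR quasi-likelihood BH-adjusted p = 0.0542, in 9 and 3 tumours). Cdkn2a rose among 6 tumour suppressor genes (0.212). Tagln rose and Myh11 fell among 8 smooth muscle genes (0.793), and Prf1 rose and Lck fell among 14 T and NK cell genes (0.0585). Csn3 fell among 8 milk protein genes (0.301), and Fabp4 and Pck1 among 8 adipocyte genes (0.212). So did Trp53bp1 and Rif1 among 12 end joining genes (0.643) and Car9 among 11 hypoxia genes (0.212). No member passed in the skeletal muscle (0.263), B and plasma cell (0.793), antigen presentation (0.793), mitochondrially encoded (0.36) and ribosomal protein lists (0.368). The 4 measured haemoglobin genes were too few for a set test. Of the Fabp4 counts in adenocarcinomas 95.9% came from tumour 52, and of the Lck counts 81.7% from tumour 26.2.

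Between L1363P carcinosarcomas (n = 9) and L1363P adenocarcinomas (n = 3) Brca1 did not pass the test (40.6 ± 10.6 against 68.0 ± 17.1 CPM, log2 fold change -0.75, SE 0.28, edgeR quasi-likelihood BH-adjusted p = 0.134, 2 of 3 adenocarcinomas above all 9). Nor did Brca2 (-0.38, adjusted p = 0.51), Trp53 (-0.22, adjusted p = 0.669) and Palb2 (-0.24, adjusted p = 0.638) pass the edgeR quasi-likelihood test with BH adjustment, with 1, 0 and 1 of 3 adenocarcinomas above all carcinosarcomas. Twist1 was higher, at 32.3 ± 14.7 against 4.35 ± 3.49 CPM (2.89, SE 0.58, edgeR quasi-likelihood BH-adjusted p = 0.00789, 9 of 9 above all 3). Fbp1, a gluconeogenic enzyme gene, was lower, at 1.03 ± 0.84 against 76.6 ± 81.2 CPM (-6.20, SE 1.02, edgeR quasi-likelihood BH-adjusted p = 0.00184, 3 of 3), and 73.4% of its adenocarcinoma counts came from tumour 26.2. Psapl1, a saposin-like gene, was lower (-7.50, SE 1.16, edgeR quasi-likelihood BH-adjusted p = 0.00118, 2 of 3), as was Mcm2, a replication helicase gene (77.9 ± 21.98 against 186.9 ± 80.3 CPM, -1.26, SE 0.25, BH-adjusted p = 0.00635, 3 of 3). Krt73, a hair follicle keratin gene, had 1 count in all carcinosarcomas against 20.8 ± 26.9 CPM. Comp, a cartilage matrix gene, was higher (5.07, SE 1.23, edgeR quasi-likelihood BH-adjusted p = 0.0234, 9 of 9 above all 3).

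In all, 88 genes were higher and 348 lower in L1363P carcinosarcomas than in adenocarcinomas, while limma on the deposited log2 values called 90 higher and 85 lower. The count of 436 fell to 91 without adenocarcinoma 26.2 and to 6 in a fit of these 2 groups alone, where Twist1 and Mcm2 no longer passed. It rose to 742 without adenocarcinoma 52. In the basal list 6 of 12 fell (7 adjusted over the list alone), including Krt17, Dsc3 and Krt15 (camera BH-adjusted p = 6.47e-06; adjusted p = 0.46 with an estimated correlation). In the squamous list 2 of 8 fell (4 alone), Krt1 and Krtdap, and in the mesenchymal list Twist1 alone of 14 rose (4 alone), with camera BH-adjusted p = 0.00586 and 0.000212 (adjusted p = 0.46 and 0.46 with an estimated correlation). Mcm2 was the only 1 of 16 proliferation genes to fall (7 alone), and 0 of 18 homologous recombination genes did (8 alone), at camera BH-adjusted p = 1.28e-06 and 2.44e-05 (adjusted p = 0.46 and 0.46 with an estimated correlation). The epithelial, collagen, endothelial, macrophage, interferon and antigen presentation sets had 0 members past the test, and 1 of 8 adipocyte genes fell.

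Between L1363P sarcomatoid tumours (n = 9) and L1363P carcinosarcomas (n = 9) Brca1 was level (37.3 ± 8.54 against 40.6 ± 10.6 CPM, log2 fold change -0.12, SE 0.20, edgeR quasi-likelihood BH-adjusted p = 0.699, 0 of 9 carcinosarcomas above all sarcomatoid tumours). Brca2 (-0.39, adjusted p = 0.222), Trp53 (0.43, adjusted p = 0.103) and Palb2 (-0.32, adjusted p = 0.22) did not pass the edgeR quasi-likelihood test with BH adjustment, with 4, 3 and 3 of 9 tumours beyond the other group. Cdh1, encoding E-cadherin, was lower in sarcomatoid tumours, at 17.9 ± 15.2 against 449.3 ± 351.1 CPM (-4.65, SE 0.84, edgeR quasi-likelihood BH-adjusted p = 0.000746, 7 of 9 carcinosarcomas above all 9). Perp was lower, at 4.10 ± 3.81 against 94.7 ± 53.2 CPM (-4.53, SE 0.73, edgeR quasi-likelihood BH-adjusted p = 0.000432, 8 of 9). Col9a1, a cartilage collagen gene, was lower (0.95 ± 0.92 against 217.8 ± 225.6 CPM, -7.82, SE 1.24, edgeR quasi-likelihood BH-adjusted p = 0.000388, 7 of 9). Csn3, a milk casein gene, was lower (-5.37, SE 1.27, edgeR quasi-likelihood BH-adjusted p = 0.00495, 7 of 9). Abcc1, a drug efflux transporter gene, was higher, at 348.1 ± 110.6 against 121.9 ± 57.9 CPM (1.51, SE 0.27, edgeR quasi-likelihood BH-adjusted p = 0.000661, 8 of 9 above all carcinosarcomas). Vim, encoding vimentin, was higher, at 3014 ± 624.4 against 1089 ± 911.7 CPM (1.47, SE 0.39, edgeR quasi-likelihood BH-adjusted p = 0.0103, 4 of 9). Gpx2 had 0 counts in sarcomatoid tumours, at least 131.3-fold less than in carcinosarcomas.

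Sarcomatoid tumours had 1203 genes higher and 2265 lower than L1363P carcinosarcomas, while limma on the deposited log2 values called 1726 higher and 1594 lower. Against only the carcinosarcomas of at least 75% epithelium the count rose from 3468 to 5560. Without L1363P carcinosarcomas 17 and 4 and KP adenocarcinoma 90.01A it was 5994, and the endothelial and neutrophil sets no longer passed (camera BH-adjusted p = 0.108 and 0.0575). With all tumours the neutrophil set was higher (median 1.46, camera BH-adjusted p = 0.0202), but not with an estimated correlation. In the epithelial list 16 of 18 fell (17 adjusted over the list alone), including Cldn3, St14 and Esrp2 (camera BH-adjusted p = 1.76e-12; adjusted p = 0.268 with an estimated correlation). In the basal list 7 of 12 fell (7 alone), including Krt17 and Dsg3, and in the luminal list 4 of 12 (5 alone), including Ehf and Elf5. In the milk protein list 6 of 8 fell (7 alone), including Csn1s1 (camera BH-adjusted p = 0.0101, 0.0187 and 0.00793 for the 3 sets; adjusted p = 0.679 with an estimated correlation for each). The mesenchymal list had 7 of 14 higher (9 alone), including S100a4, and the collagen list 6 of 15 (12 alone), including Fbn1 and Col5a2. The drug efflux list had 3 of 5 higher (3 alone), including Abcb1a (camera BH-adjusted p = 1.71e-06, 1.14e-06 and 0.000456 for the 3 sets; adjusted p = 0.268 with an estimated correlation for each). The endothelial list had 2 of 10 higher (6 alone), Cdh5 and Tie1, and the macrophage list 3 of 11 (4 alone), Mrc1, Csf1r and Cd68 (camera BH-adjusted p = 0.00717 and 0.000456; adjusted p = 0.679 with an estimated correlation for both).

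Within the 9 L1363P carcinosarcomas, whose labelled epithelium ran from 2 to 98%, Brca1 (log2 slope 0.01 per 10 percentage points, adjusted p = 0.877), Brca2 (0.07, adjusted p = 0.441), Trp53 (-0.01, adjusted p = 0.852) and Palb2 (0.04, adjusted p = 0.539) did not follow the percentage by edgeR's quasi-likelihood test with BH adjustment in these 9 tumours. Csn2, the beta-casein gene, rose by 1.26 per 10 points (SE 0.27, edgeR quasi-likelihood BH-adjusted p = 0.0233), with 6 of 6 tumours of at least 75% epithelium above the 3 of 40% or less. Pdgfra, a fibroblast receptor gene, fell by 0.43 per 10 points (SE 0.07, edgeR quasi-likelihood BH-adjusted p = 0.00832, 3 of 3 low tumours above all 6). Prf1, the perforin gene, fell by 0.63 (SE 0.08, edgeR quasi-likelihood BH-adjusted p = 0.00392, 3 of 3). Yap1, encoding a growth regulator of the Hippo pathway, fell by 0.64 (SE 0.08, edgeR quasi-likelihood BH-adjusted p = 0.00445, 2 of 3), and Abcb1b fell by 0.39 (SE 0.07, BH-adjusted p = 0.0137, 3 of 3). Glycam1, a mucin gene of milk, had 1 count in the 3 low tumours against 88.8 ± 170.9 CPM in the 6 others.

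The slope was positive for 379 genes and negative for 843 of 14645. Among the 6 tumours of at least 75% epithelium the 1222 calls fell to 0 and Csn2, Yap1 and Abcb1b turned direction (slopes -0.07, 0.14 and 0.42). In the milk protein list 6 of 8 rose with the percentage (7 adjusted over the list alone), including Csn1s1 and Lalba (camera BH-adjusted p = 1.01e-07; adjusted p = 0.167 with an estimated correlation). In the mesenchymal list 4 of 14 fell (7 alone), including S100a4, Zeb2 and Vim, and in the T and NK cell list 6 of 13 (10 alone), including Ncr1 and Nkg7. In the macrophage list 9 of 11 fell (10 alone), including Lyz2 and Csf1r (camera BH-adjusted p = 4.21e-08, 1.76e-10 and 8.98e-10 for the 3 sets; adjusted p = 0.15, 0.142 and 0.194 with an estimated correlation). Collagen genes fell for 4 of 15 (7 alone), including Dcn, and 0 of 18 epithelial genes passed (camera BH-adjusted p = 2.63e-06 and 1.01e-07; adjusted p = 0.403 and 0.456 with an estimated correlation). Across 28 list scores, exact permutation tests of Pearson correlation passed for 7 in these 9 tumours: luminal epithelial (two-sided BH-adjusted p = 0.0468), milk protein (0.0119), mesenchymal (0.0119), T and NK cell (0.0119), B and plasma cell (0.041), macrophage (0.041) and drug efflux (0.0199). Without tumours 4 and 17, 0 of 28 passed, and by Spearman correlation 0 of 28 in all 9.

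**Figure D3:**
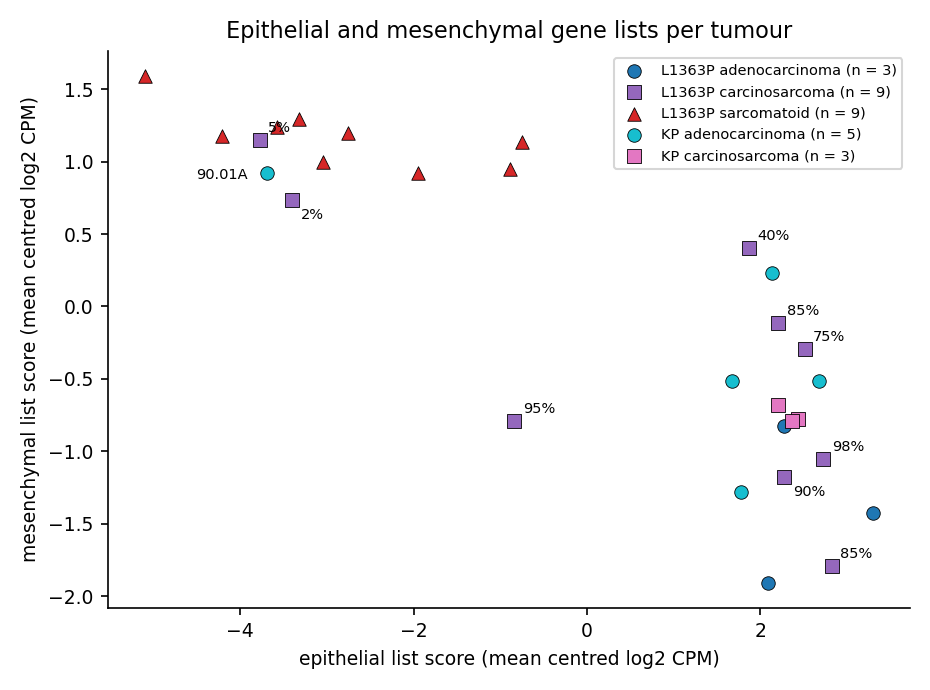
Mesenchymal list score against epithelial list score (mean centred log2 CPM) in 29 tumours, coloured by group, with the labelled epithelial percentage of each L1363P carcinosarcoma. Carcinosarcomas 17 and 4 and KP adenocarcinoma 90.01A lie with the sarcomatoid tumours.

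Met and Yap1 were each very high in subsets of tumours, together with genes beside them. Met, encoding the HGF receptor on chromosome 6 (17463800 to 17573980), reached at least 10 times its median of 324.8 CPM in 8 of 29 tumours: L1363P carcinosarcomas 53, 54.1, 54.2 and 21.1, all 3 KP carcinosarcomas and KP adenocarcinoma 39. Its median excess there was 35.5-fold, beside 32.4-fold for Tes, 19.9-fold for Capza2 and 48.4-fold for Cftr, but 0.892-fold for Cav1. Yap1, on chromosome 9 (7931999 to 8004596), reached at least 10 times its median of 361.8 CPM in 12 of 29 tumours: 8 of 9 sarcomatoid tumours (all but 10), L1363P carcinosarcomas 17 and 4, KP adenocarcinoma 90.01A and KP carcinosarcoma 5. Its median excess was 24.6-fold, beside 27.7-fold for Birc2, 25.4-fold for Birc3, 42.5-fold for Dcun1d5 and 14.8-fold for Mmp3. Met was also lower in sarcomatoid tumours than in L1363P carcinosarcomas (281.4 ± 84.6 against 5392 ± 6104 CPM, log2 fold change -4.26, SE 1.07, edgeR quasi-likelihood BH-adjusted p = 0.00735, 6 of 9 carcinosarcomas above all 9), a call lost with limma on the deposited log2 values. These regions were examined after the values had been seen, and DNA copy number was not analysed here.

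**Figure D4:**
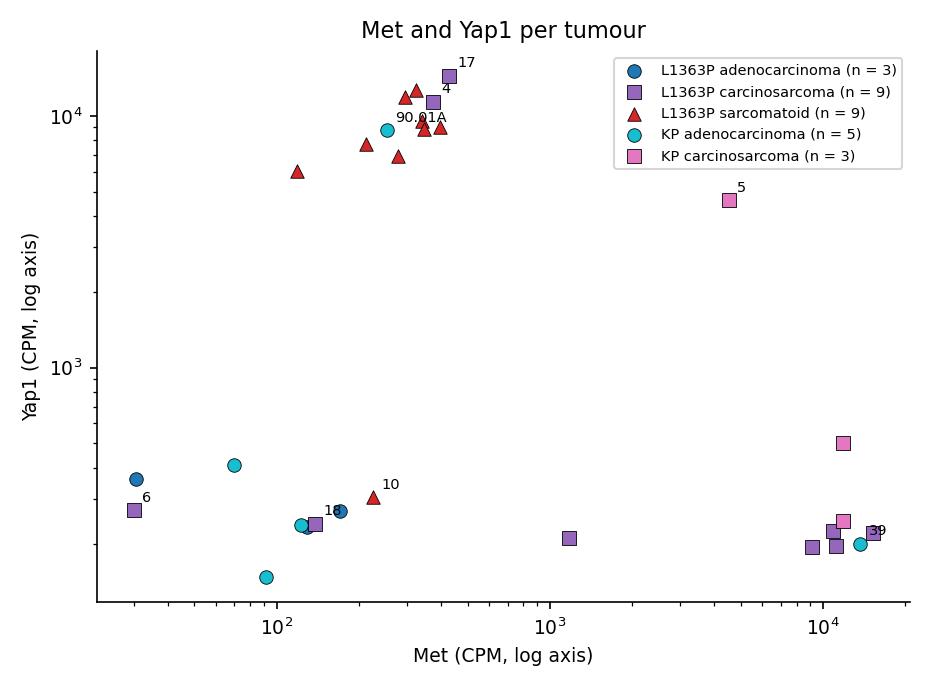
Yap1 against Met in CPM on log axes in 29 tumours, coloured by group. Met was high in 4 L1363P carcinosarcomas, all 3 KP carcinosarcomas and KP adenocarcinoma 39, Yap1 in 8 of 9 sarcomatoid tumours, 2 carcinosarcomas of low epithelial content and KP adenocarcinoma 90.01A, and both in KP carcinosarcoma 5.

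KP carcinosarcomas (n = 3) differed from KP adenocarcinomas (n = 5) in 0 genes, with 1926 at unadjusted p < 0.05, 183 by the DESeq2 Wald test and 1 by limma. Brca1 was 65.2 ± 14.4 against 34.0 ± 15.2 CPM (log2 fold change 0.94, SE 0.31, edgeR quasi-likelihood BH-adjusted p = 0.342, 2 of 3 carcinosarcomas above all 5), and Brca2 (0.32, adjusted p = 0.744), Trp53 (-0.19) and Palb2 (0.43, adjusted p = 0.556) did not pass either. The count became 1 without KP carcinosarcoma 130.10A, 2 without carcinosarcoma 5, 2 without adenocarcinoma 39 and 2 in a fit of these 2 groups alone. With 0 members past the test, camera placed the proliferation, interferon and milk protein sets higher (median log2 fold changes 0.65, 1.06 and 3.40, camera BH-adjusted p = 2.09e-08, 1.78e-06 and 2.56e-06; adjusted p = 0.441, 0.592 and 0.441 with an estimated correlation). The adipocyte set was lower (-5.02, 0 of 8 past the test, 6 lower adjusted over the list alone, camera BH-adjusted p = 0.000226; adjusted p = 0.56 with an estimated correlation). Without L1363P carcinosarcomas 17 and 4 and KP adenocarcinoma 90.01A the interferon median was 1.86. The neutrophil median then turned from -0.82 to 1.245 (camera BH-adjusted p = 0.535 and 0.00199). The epithelial set was lost (0.0149 and 0.474) and the basal set was called lower (0.0841 and 0.000311). With an estimated correlation the neutrophil, epithelial and basal sets did not pass (adjusted p = 0.439, 0.852 and 0.356).

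The carcinosarcoma difference of L1363P mice was set against that of KP mice (20 tumours). Brca1 (difference of log2 fold changes -1.68, adjusted p = 0.125), Brca2 (-0.70, adjusted p = 0.495), Trp53 (-0.03, adjusted p = 0.975) and Palb2 (-0.66, adjusted p = 0.426) did not pass edgeR's quasi-likelihood test with BH adjustment over these 20 tumours. Pold1, encoding the catalytic subunit of DNA polymerase delta, differed by -2.09 (SE 0.33, edgeR quasi-likelihood BH-adjusted p = 0.0131), at 22.6 ± 5.80 CPM in L1363P carcinosarcomas and KP adenocarcinomas (n = 14) and 44.9 ± 13.0 in the other 2 groups (n = 6), with 5 of 6 above all 14. B4galnt2, a glycosyltransferase gene, was the only other gene called, and 92.5% of its counts in the 6 came from L1363P adenocarcinoma 7.2. Both were negative, with 2422 genes at unadjusted p < 0.05, 390 called by the DESeq2 Wald test and 3 by limma. The count of 2 became 116 without KP adenocarcinoma 131.03A, 36 without L1363P adenocarcinoma 7.2 and 11 without 52. It became 0 without KP carcinosarcoma 5, in a fit of these groups alone, with carcinosarcomas of at least 75% epithelium, or without L1363P carcinosarcomas 17 and 4 and KP adenocarcinoma 90.01A. Among 16 proliferation genes 0 passed (11 lower adjusted over the list alone), and among 18 homologous recombination genes 0 (4 lower alone), with set medians of -1.33 and -0.69 (camera BH-adjusted p = 2.21e-16 and 1.91e-08; adjusted p = 0.0699 and 0.0699 with an estimated correlation). The mesenchymal set went the other way (median 2.12, 0 of 14 past the test, 3 alone, camera BH-adjusted p = 1.78e-05; adjusted p = 0.374 with an estimated correlation). Without tumours 17, 4 and 90.01A its median was 1.32 (camera BH-adjusted p = 0.00665; adjusted p = 0.596 with an estimated correlation).

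L1363P adenocarcinomas (n = 3) and KP adenocarcinomas (n = 5) were compared within 1 run. Brca1 was 68.0 ± 17.1 against 34.0 ± 15.2 CPM (log2 fold change 1.00, SE 0.31, edgeR quasi-likelihood BH-adjusted p = 0.153, 2 of 3 above all 5), and Brca2 (1.07, adjusted p = 0.175), Trp53 (0.17, adjusted p = 0.828) and Palb2 (0.61, adjusted p = 0.299) did not pass. Hjurp, a centromere chaperone gene, was higher in L1363P tumours, at 236.7 ± 148.7 against 81.4 ± 23.0 CPM (1.54, SE 0.27, edgeR quasi-likelihood BH-adjusted p = 0.019, 3 of 3 above all 5). Pole2, a replicative polymerase gene, was 31.3 ± 17.5 against 10.9 ± 1.92 CPM (1.52, SE 0.27, edgeR quasi-likelihood BH-adjusted p = 0.019, 3 of 3), and Pcna, the sliding clamp gene, 148.2 ± 42.8 against 75.4 ± 12.8 CPM (0.98, SE 0.21, BH-adjusted p = 0.0445, 3 of 3). Slit2, a guidance cue gene, was lower, at 14.1 ± 9.43 against 73.1 ± 22.9 CPM (-2.38, SE 0.50, edgeR quasi-likelihood BH-adjusted p = 0.0445, 5 of 5 KP tumours above all 3). Agtrap, encoding an angiotensin receptor-associated protein, was lower (-1.19, SE 0.21, edgeR quasi-likelihood BH-adjusted p = 0.0228, 5 of 5).

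Between these adenocarcinomas 23 genes were higher and 11 lower in L1363P tumours. The 34 calls became 283 without KP adenocarcinoma 131.03A, 129 without L1363P adenocarcinoma 7.2, 61 without 52 and 16 without 26.2. They became 14 without KP adenocarcinoma 39, 11 without 90.01A, 2 without 90.01A and L1363P carcinosarcomas 17 and 4, 7 without 40, and 0 in a fit of these 2 groups alone. Pcna alone of 16 proliferation genes rose (12 adjusted over the list alone), and 0 of 18 homologous recombination genes did (9 alone), with set medians of 0.89 and 0.68 (camera BH-adjusted p = 1.16e-13 and 1.19e-10; adjusted p = 0.0933 and 0.0713 with an estimated correlation). Of 10 endothelial genes 0 fell (7 alone), with a set median of -1.27 (camera BH-adjusted p = 2.49e-08; adjusted p = 0.101 with an estimated correlation). The collagen set had 0 of 15 past the test, with a median of -1.27 (camera BH-adjusted p = 3.53e-06; adjusted p = 0.239 with an estimated correlation). Fabp4 rose among adipocyte genes, with 95.9% of its L1363P counts in tumour 52.

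L1363P carcinosarcomas (n = 9) and KP carcinosarcomas (n = 3) differed in 0 genes, with 741 at unadjusted p < 0.05, 6 by the DESeq2 Wald test and 2 without the count filter. Brca1 was 40.6 ± 10.6 against 65.2 ± 14.4 CPM (log2 fold change -0.69, SE 0.28, edgeR quasi-likelihood BH-adjusted p = 0.935, 2 of 3 KP tumours above all 9), and Brca2 (0.36, adjusted p = 0.947), Trp53 (0.13, adjusted p = 0.971) and Palb2 (-0.05, adjusted p = 0.996) did not pass. The count became 1 without KP carcinosarcoma 26.02A and 2 without 5. With 0 members past the test, camera placed the interferon, proliferation and epithelial sets lower in L1363P tumours (medians -0.95, -0.32 and -0.41, camera BH-adjusted p = 2.62e-08, 7.81e-06 and 0.000151; adjusted p = 0.63 with an estimated correlation for each). Without L1363P carcinosarcomas 17 and 4 and KP adenocarcinoma 90.01A the epithelial set no longer passed (median -0.05, camera BH-adjusted p = 0.205), while the interferon and proliferation sets did (-1.32 and -0.28, camera BH-adjusted p = 2.34e-18 and 5.14e-05; adjusted p = 0.405 and 0.656 with an estimated correlation).

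The remaining comparisons crossed sequencing runs, and genotype could not be separated from run. As a yardstick from 2 runs alone, KB2P tumours of run 2749 (n = 12) and run 2459 (n = 9) differed in 98 genes, 38 higher and 60 lower (793 by the DESeq2 Wald test and 50 by limma). Brca1 (log2 fold change 0.03, adjusted p = 0.954), Brca2 (0.36, adjusted p = 0.316), Trp53 (-0.29, adjusted p = 0.46) and Palb2 (0.03, adjusted p = 0.95) did not pass edgeR's quasi-likelihood test with BH adjustment, with 3, 4, 1 and 1 tumours beyond the other run. Lars2, a mitochondrial tRNA ligase gene, was 1181 ± 310.4 against 319.4 ± 56.8 CPM (1.89, SE 0.18, edgeR quasi-likelihood BH-adjusted p = 1.17e-06, 12 of 12 above all 9). Scand1, a small GC-rich gene, was lower in run 2749 (-1.52, SE 0.24, edgeR quasi-likelihood BH-adjusted p = 0.00162, 9 of 9 of run 2459 above all 12). Among 11 antigen presentation genes 0 passed (7 lower adjusted over the list alone), and among 6 mitochondrially encoded genes mt-Nd5 rose (5 alone), at camera BH-adjusted p = 4.03e-07 and 2.54e-07 (adjusted p = 0.537 and 0.263 with an estimated correlation). The ribosomal protein gene Rps6 had medians of 2.84 and 3.88 CPM in KB2P runs 2749 and 2459. Within KB1P its median was 211.7 CPM in run 3528 but 3.35 and 3.24 in runs 1857 and 2119. The 98 calls therefore do not give the scale of run differences in the comparisons below.

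L1363P adenocarcinomas (n = 3) had more Brca1 than KB1P adenocarcinomas (n = 21, both titles), at 74.9 ± 18.3 against 29.0 ± 8.14 CPM (log2 fold change 1.40, SE 0.26, edgeR quasi-likelihood BH-adjusted p = 0.000133, 3 of 3 above all 21). Brca2 (-0.02, adjusted p = 0.987), Trp53 (0.10, adjusted p = 0.896) and Palb2 (0.07, adjusted p = 0.927) did not pass edgeR's quasi-likelihood test with BH adjustment, with 1 of 21, 0 of 3 and 0 of 3 tumours beyond the other group. Rps6, a ribosomal protein gene, was 327.1 ± 66.3 against 23.3 ± 64.1 CPM (5.01, SE 0.54, edgeR quasi-likelihood BH-adjusted p = 1.6e-10, 3 of 3). The KB1P mean joins 2 levels. Rps6 had 210.1 and 213.3 CPM in the 2 tumours of run 3528. Its medians were 3.35, 3.24, 2.04 and 2.52 CPM in runs 1857, 2119, 1725 and 1756. Pcna was higher (0.84, SE 0.19, edgeR quasi-likelihood BH-adjusted p = 0.00279, 1 of 3 above all 21). Scand1 was lower, at 0.34 ± 0.14 against 26.3 ± 18.9 CPM (-6.14, SE 0.81, edgeR quasi-likelihood BH-adjusted p = 5.23e-08, 21 of 21 KB1P tumours above all 3). Wnt1, a mammary oncogene, was lower (0.09 ± 0.04 against 60.4 ± 122.9 CPM, -8.50, SE 2.57, edgeR quasi-likelihood BH-adjusted p = 0.0356, 11 of 21 above all 3). Its median was 1.62 CPM in KB1P-titled and 0 in KB1PM-titled tumours, so a few tumours carried the KB1P mean.

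In this comparison 490 genes were higher and 434 lower in L1363P adenocarcinomas, while limma on the deposited log2 values called 315 higher and 587 lower. The 924 calls fell to 178 against the 2 KB1P tumours of run 3528 alone, where Rps27, Rpl19, Rps29, Rps13 and Rps18 turned direction, and to 505 when 1 L1363P tumour was left out. In the ribosomal protein list 5 of 10 rose (5 adjusted over the list alone), including Rpl3 and Rpl7, the only set called (camera BH-adjusted p = 1.49e-13; adjusted p = 0.00493 with an estimated correlation).

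Against KB2P adenocarcinomas (n = 23), Brca1 in L1363P adenocarcinomas (n = 3) did not pass the test (74.9 ± 18.3 against 60.1 ± 26.7 CPM, log2 fold change 0.32, SE 0.28, edgeR quasi-likelihood BH-adjusted p = 0.511, 0 of 3 above all 23). Brca2 (0.07, adjusted p = 0.925), Trp53 (-0.21, adjusted p = 0.66) and Palb2 (0.14, adjusted p = 0.786) did not pass edgeR's quasi-likelihood test with BH adjustment, with 0 of 3, 15 of 23 and 0 of 3 tumours beyond the other group. Nr1h5, a nuclear receptor gene, was 24.9 ± 6.49 against 0.17 ± 0.28 CPM (7.17, SE 0.60, edgeR quasi-likelihood BH-adjusted p = 4.07e-15, 3 of 3 above all 23). H2-Eb1, an MHC class II gene, was lower, at 2.83 ± 1.10 against 96.5 ± 136.1 CPM (-5.09, edgeR quasi-likelihood BH-adjusted p = 0.00262, 23 of 23 KB2P tumours above all 3). Pcna was higher, at 163.2 ± 46.1 against 82.2 ± 18.8 CPM (0.99, SE 0.19, edgeR quasi-likelihood BH-adjusted p = 0.000145, 3 of 3), and Xrcc3, a homologous recombination gene, lower (-1.68, SE 0.35, BH-adjusted p = 0.000602, 22 of 23). Hba-a2, a haemoglobin gene, had 0 counts in L1363P adenocarcinomas, at least 57.0-fold less than in KB2P tumours. Its mean was 3.01 CPM in KB2P tumours and at most 0.028 in every other group. Rps3a3 had a mean of 128.5 CPM in KB2P tumours and at most 0.333 elsewhere, while Rps3a1 had 7.31 and at least 83.9. In single KB2P libraries Rps3a3 lay at 61.8 to 237.1 CPM, against at most 0.851 in any other library. Rps3a1 lay at 3.40 to 14.3 CPM, against at least 47.8. The 2 genes thus exchanged levels in every KB2P library, and the cause was not tested. Calls of genes with close copies are therefore uncertain in every comparison with KB2P tumours. Whether reads of other similar genes were assigned alike was not tested.

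Here 816 genes were higher and 867 lower, while limma on the deposited log2 values called 597 higher and 1040 lower. The 1683 calls fell to 924 in a fit of these 2 groups alone and to 863 when 1 L1363P tumour was left out. In the ribosomal protein list 6 of 10 rose (6 adjusted over the list alone), including Rps6 and Rplp0 (camera BH-adjusted p = 1.24e-10; adjusted p = 0.0212 with an estimated correlation). Rps6 lay at 3.66 ± 1.32 CPM in KB2P tumours. Its median was as low in KB1P runs 1857 and 2119 (3.35 and 3.24 CPM) but not in KB1P run 3528 (211.7). This rise could therefore not be told from a difference between runs. In the milk protein list Csn1s2a and Lalba rose among 8 (4 alone), and in the epithelial list Krt7 and Krt8 among 18 (2 alone), at camera BH-adjusted p = 0.0197 for both (adjusted p = 0.997 with an estimated correlation). Of the Csn1s2a counts 97.0% came from tumour 26.2, and of the Krt7 counts 91.9% from tumour 52.

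KP adenocarcinomas (n = 5) had less Brca2 than KB1P adenocarcinomas (n = 21), at 23.3 ± 9.83 against 50.1 ± 24.3 CPM (log2 fold change -1.08, SE 0.29, edgeR quasi-likelihood BH-adjusted p = 0.00353, 17 of 21 KB1P tumours above all 5). Brca1 (0.40, adjusted p = 0.198), Trp53 (-0.08, adjusted p = 0.826) and Palb2 (-0.55, adjusted p = 0.072) did not pass edgeR's quasi-likelihood test with BH adjustment, with 1 of 5, 7 of 21 and 6 of 21 tumours beyond the other group. Pecam1, an endothelial adhesion gene, was higher, at 175.7 ± 92.0 against 45.2 ± 17.4 CPM (1.96, SE 0.24, edgeR quasi-likelihood BH-adjusted p = 1.72e-09, 4 of 5 above all 21). Col3a1, a fibrillar collagen gene, was higher, at 3760 ± 2239 against 717.7 ± 684.1 CPM (2.44, SE 0.46, edgeR quasi-likelihood BH-adjusted p = 3.55e-05, 3 of 5). Mcl1, a survival gene, was higher (1.53, SE 0.23, edgeR quasi-likelihood BH-adjusted p = 3.26e-07, 5 of 5). Xrcc3 was lower, at 6.66 ± 2.98 against 21.3 ± 7.24 CPM (-1.68, SE 0.28, edgeR quasi-likelihood BH-adjusted p = 5.01e-06, 21 of 21), and Mcm2 was lower (-0.88, SE 0.23, BH-adjusted p = 0.00303, 19 of 21).

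KP adenocarcinomas had 2769 genes higher and 2276 lower than KB1P tumours. Without KP adenocarcinoma 90.01A the 5045 calls fell to 3105, Dcn moved from 4.53 to 3.10 and Mrc1 from 2.14 to 1.31, and the macrophage genes Lyz2 (1.175), Fcgr1 (0.96) and C1qa (0.85) no longer passed. Against run 3528 alone 1471 were called, and with the KB1PM tumours of run 1756 alone 3143. In the collagen list 12 of 15 rose (12 adjusted over the list alone), including Postn and Lum, and in the macrophage list 11 of 11 (11 alone), including Lyz2. In the endothelial list 8 of 10 rose (8 alone), including Cdh5 and Emcn, and in the mesenchymal list 6 of 14 (7 alone), including Sparc and Cdh11 (camera BH-adjusted p = 2.94e-09, 4.59e-06, 4.89e-06 and 0.000991; adjusted p = 0.134, 0.269, 0.269 and 0.269 with an estimated correlation). Proliferation genes fell for 8 of 16 (9 alone), including Mki67 and Plk1, and homologous recombination genes for 6 of 18 (6 alone), including Bard1 and Fancd2 (camera BH-adjusted p = 0.000587 and 0.00141; adjusted p = 0.356 and 0.269 with an estimated correlation). All 8 skeletal muscle genes rose (8 alone), including Tnnt3, with 72.2% of its KP counts in tumour 40 (camera BH-adjusted p = 0.000529; adjusted p = 0.356 with an estimated correlation). Their mean was high only in KP tumours 131.03A (82.4 CPM) and 40 (289.8), with 0.565 to 1.52 CPM in the 3 others. Without those libraries Acta1 (-0.84), Ckm (-3.61), Des (-0.31) and Mybpc1 (-0.66) turned to lower.

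Against KB2P adenocarcinomas (n = 23), KP adenocarcinomas (n = 5) had less Brca1, at 37.5 ± 16.9 against 60.1 ± 26.7 CPM (log2 fold change -0.68, SE 0.25, edgeR quasi-likelihood BH-adjusted p = 0.0259, 8 of 23 KB2P tumours above all 5). Brca2 was lower too (23.3 ± 9.83 against 46.4 ± 19.01 CPM, -0.99, SE 0.29, edgeR quasi-likelihood BH-adjusted p = 0.00508, 16 of 23). Trp53 (-0.38, adjusted p = 0.16) and Palb2 (-0.47, adjusted p = 0.1) did not pass edgeR's quasi-likelihood test with BH adjustment, with 14 and 5 of 23 beyond the KP tumours. Cdh11, a mesenchymal cadherin gene, was higher, at 71.9 ± 51.3 against 11.7 ± 6.92 CPM (2.62, SE 0.42, edgeR quasi-likelihood BH-adjusted p = 9.1e-07, 5 of 5 above all 23). Pecam1 was higher (1.94, SE 0.23, edgeR quasi-likelihood BH-adjusted p = 6.59e-10, 4 of 5). Xrcc3 was lower, at 6.66 ± 2.98 against 36.1 ± 20.8 CPM (-2.44, SE 0.30, edgeR quasi-likelihood BH-adjusted p = 1.07e-09, 23 of 23), as was H2-Eb1 (-4.26, SE 0.89, BH-adjusted p = 0.000121, 23 of 23).

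Here 3182 genes were higher and 3353 lower. Without KP adenocarcinoma 90.01A Mmp3 moved from 8.31 to 3.57, Il1rl1 from 8.54 to 5.47, Dcn from 5.34 to 3.92 and Abcb1b from 3.34 to 2.31, and all still passed. In the collagen list 11 of 15 rose (12 adjusted over the list alone), including Lum and Col3a1, in the macrophage list 11 of 11 (11 alone), including Mrc1, and in the neutrophil list 6 of 6 (6 alone), including Csf3r (camera BH-adjusted p = 5.97e-09, 6.58e-07 and 0.00471; adjusted p = 0.168, 0.3 and 0.424 with an estimated correlation). The neutrophil score was 3.26 in 90.01A and -4.05 to 0.65 in the 4 other KP tumours. Without 90.01A the neutrophil genes Csf3r (1.40) and S100a9 (1.935) no longer passed, while Retnlg (3.03), Cxcr2 (2.71) and Mrc1 (2.45) did. Proliferation genes fell for 12 of 16 (13 alone), including Plk1 and E2f1, and homologous recombination genes for 7 of 18 (7 alone), including Bard1 and Fancd2 (camera BH-adjusted p = 0.000133 and 0.0159; adjusted p = 0.3 and 0.424 with an estimated correlation). Drug efflux genes rose for 3 of 5 (4 alone), including Abcb1a (camera BH-adjusted p = 0.00241; adjusted p = 0.26 with an estimated correlation).

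KB1P adenocarcinomas (n = 21) had less Brca1 than KB2P adenocarcinomas (n = 23), at 29.0 ± 8.14 against 60.1 ± 26.7 CPM (log2 fold change -1.08, SE 0.15, edgeR quasi-likelihood BH-adjusted p = 7.78e-08, 18 of 23 KB2P tumours above all 21). Brca2 (0.09, adjusted p = 0.773), Trp53 (-0.31, adjusted p = 0.102) and Palb2 (0.07, adjusted p = 0.783) did not pass edgeR's quasi-likelihood test with BH adjustment, with 1 of 21, 5 of 23 and 1 of 21 beyond the other group. Wnt1 was higher in KB1P tumours, at 60.4 ± 122.9 against 0.07 ± 0.10 CPM (8.80, SE 1.00, edgeR quasi-likelihood BH-adjusted p = 2.95e-10, 9 of 21 above all 23). Its level was uneven, with 352.7, 334.6 and 336.9 CPM in KB1P-titled tumours 1, 2 and 4. The median was 1.62 CPM in KB1P-titled and 0 in KB1PM-titled tumours. H2-Eb1 was lower, at 4.24 ± 4.54 against 96.5 ± 136.1 CPM (-4.51, SE 0.47, edgeR quasi-likelihood BH-adjusted p = 1.28e-11, 19 of 23 KB2P tumours above all 21). Atm, the damage kinase gene, was higher, at 83.5 ± 34.3 against 42.9 ± 15.6 CPM (0.95, SE 0.16, edgeR quasi-likelihood BH-adjusted p = 7.84e-06, 9 of 21).

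In KB1P tumours 994 genes were higher and 1445 lower than in KB2P tumours, while limma on the deposited log2 values called 913 higher and 884 lower. The 2439 calls fell to 417 with KB1P run 1857 alone, 954 with KB1P-titled tumours alone and 1219 with KB2P run 2749 alone. They fell to 127 with the tumour number as a block, in the libraries of shared numbers. No list moved as a set. In the B and plasma cell list 4 of 8 fell (6 adjusted over the list alone), including Ms4a1, Cd79a and Cd79b (camera BH-adjusted p = 0.125), and in the milk protein list 4 of 8 rose, including Csn2 and Csn1s1, and Glycam1 fell.

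Between KB1PM-titled (n = 10) and KB1P-titled tumours (n = 11) Brca1 (24.4 ± 6.36 against 33.2 ± 7.48 CPM, log2 fold change -0.44, SE 0.21, edgeR quasi-likelihood BH-adjusted p = 0.391, 5 of 11 KB1P tumours above all 10) did not pass the test. Brca2 (-0.41, adjusted p = 0.537), Trp53 (-0.23, adjusted p = 0.696) and Palb2 (-0.27, adjusted p = 0.666) did not pass edgeR's quasi-likelihood test with BH adjustment, with 3, 1 and 1 of 11 beyond the other group. Abcb1b was higher in KB1PM tumours, at 91.3 ± 77.5 against 4.77 ± 4.69 CPM (4.26, SE 0.60, edgeR quasi-likelihood BH-adjusted p = 4.19e-06, 10 of 10 above all 11). Abcb1a was not (-0.75, edgeR quasi-likelihood BH-adjusted p = 0.557 in 10 and 11 tumours). The labels give both titles the genotype KB1P and do not say what sets them apart. Gene totals do not show whether the Abcb1b reads of KB1PM tumours come from an intact gene. Rb1, a cell cycle suppressor gene, was higher, at 68.1 ± 34.1 against 33.3 ± 8.59 CPM (1.03, SE 0.25, edgeR quasi-likelihood BH-adjusted p = 0.0158, 6 of 10). Pcna was lower (-0.63, SE 0.15, edgeR quasi-likelihood BH-adjusted p = 0.0151, 8 of 11 KB1P tumours above all 10).

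Of these tumours' genes, 87 were higher and 77 lower in KB1PM. The 164 calls became 17 without KB1P run 3528, 87 without ribosomal protein genes and pseudogenes, 4 by limma and 2 in a fit of these 2 groups alone. Prr9, Tchh and Krt27, hair and skin genes, drew 99.8%, 98.6% and 97.7% of their KB1PM counts from tumour 2. In the ribosomal protein list 4 of 10 fell (4 adjusted over the list alone), including Rps6 and Rpl3, and in the drug efflux list Abcb1b alone of 5 rose (1 alone), at camera BH-adjusted p = 3.01e-05 and 0.047 (adjusted p = 0.439 and 0.77 with an estimated correlation). The Rps6 median was 211.7 CPM in KB1P run 3528, but 3.35 and 3.24 in KB1P runs 1857 and 2119. It was 2.04 and 2.52 CPM in KB1PM runs 1725 and 1756, so most of the Rps6 fall came from run 3528.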

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

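The tests of the L1363P and KB1P calls, of KP adenocarcinoma 90.01A and of the Met and Yap1 regions were chosen only after the results had been seen, while the splits of libraries were fixed before the data were examined.

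Single tumours stood far from their group by Dixon's gap test on 104 sets of group values, which found 10, where chance alone would give about 1 in 20. L1363P carcinosarcoma 18 had 12.9 CPM of Brca2 (29.4 to 65.6 in the 8 others) and a proliferation score of -1.12 (-0.37 to 0.31). L1363P carcinosarcoma 6 had a skeletal muscle score of 6.47 (-2.63 to 1.83) and a tumour suppressor score of -1.19 (-0.16 to 0.43). L1363P carcinosarcoma 4 had a B and plasma cell score of 2.38 (-1.32 to 0.47). Sarcomatoid tumour 9.1 had 71.5 CPM of Trp53 (15.3 to 32.5), and sarcomatoid tumour 29 a haemoglobin score of 3.81 (-0.71 to 0.76). KP adenocarcinoma 90.01A had an epithelial score of -3.70 (1.67 to 2.68 in the 4 others). KP adenocarcinoma 131.03A had an end joining score of 0.24 (-0.21 to -0.10) and a ribosomal protein score of 0.56 (-0.21 to -0.06).

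The test of whether the carcinosarcoma difference was the same in L1363P and KP mice found Pold1 (-2.09, edgeR quasi-likelihood BH-adjusted p = 0.0131) and B4galnt2 (-7.12, BH-adjusted p = 0.0203) over 20 tumours. With camera at the preset correlation it also found the proliferation set (median -1.33, BH-adjusted p = 2.21e-16), homologous recombination (-0.69, 1.91e-08), epithelial (-1.21, 1.78e-05), mesenchymal (2.12, 1.78e-05), collagen (1.74, 0.000165), endothelial (1.01, 0.00155), macrophage (1.90, 0.00155), drug efflux (1.202, 0.0066) and p53 target genes (0.79, 0.0136). With an estimated correlation none passed (adjusted p = 0.0699, 0.0699, 0.481, 0.374, 0.374, 0.435, 0.498, 0.374 and 0.0699). Without L1363P carcinosarcomas 17 and 4 and KP adenocarcinoma 90.01A, left out only after the results had been seen, the values of Pold1 (-2.13) and B4galnt2 (-7.13) hardly moved but neither passed. The epithelial, mesenchymal and collagen medians shrank to -0.655, 1.32 and 0.93 (camera BH-adjusted p = 0.0315, 0.00665 and 0.0127), and the macrophage (0.25, BH-adjusted p = 0.366) and drug efflux sets (0.33, BH-adjusted p = 0.0629) no longer passed. With an estimated correlation the epithelial, mesenchymal and collagen sets did not pass either (camera adjusted p = 0.761, 0.596 and 0.724).

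The 924 calls between L1363P and KB1P adenocarcinomas come from libraries of different runs. Of these calls 21.8% were ribosomal protein genes or pseudogenes, and 65.2% stayed with a correction for GC content per library. GC bias removed by that correction could therefore not account for most of the calls. Reads shared with pseudogenes could not be excluded, since other genes that share reads with pseudogenes were not counted. The 2 causes were not tested together. The ribosomal protein genes differed between runs within KB1P. The 53 that were higher in L1363P tumours were 3.51 log2 units higher (median) in KB1P run 3528 than in the other KB1P-titled tumours (1 of 55 splits as large, exact permutation p = 0.0182, highest other 1.79). Their median log2 fold change in L1363P against KB1P tumours was 2.61. Calls of these genes can therefore not be taken as a difference of genotype. For the remaining calls run and genotype could not be told apart, since all L1363P libraries came from run 5625 and no KB1P library did. Against the 2 libraries of run 3528, also another run, 178 were called.

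KP adenocarcinoma 90.01A, labelled 100% epithelial, lay nearest to the sarcomatoid mean (correlation 0.818). A swap with one of the 9 sarcomatoid tumours was excluded, since 0 of them lay nearest to a mean other than the sarcomatoid one, as 4 of 4 other KP adenocarcinomas did. Other cells mixed into a tumour with the epithelial content of the other KP adenocarcinomas were excluded, since its epithelial genes had a median of 0.733% of their level in the other KP adenocarcinomas, where the lowest other had 55.1%. A sample taken largely from non-epithelial tissue was not tested. A single wrong label could not be told from a KP adenocarcinoma of this kind, although Yap1 was 21.4 times that of the highest other KP adenocarcinoma, as in most sarcomatoid tumours.

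Met and Yap1 may mark gains of copies of their regions. In 8 of 8 tumours with Met at 10 times its median or more, its neighbours lay above the 99th percentile of all 15109 windows of the genome (lowest 99.9), and so did the neighbours of Yap1 in 12 of 12 (15107 windows, lowest 99.9). Of the other tumours, L1363P carcinosarcoma 45, with 1175 CPM of Met, also had neighbours of Met above it (99.8). Reads shared between the paralogs Birc2 and Birc3 could not account for the rise around Yap1. There 5 other genes, Dcun1d5, Tmem123, Cfap300, Cep126 and Dync2h1, had a median of 25.6 times their level over 29 tumours. Mmp13 and Mmp12 rose less (median 2.25-fold and 2.05-fold in the 12 tumours). Whether Birc2 and Birc3 share reads with each other was not tested. Both are RNA values, and copy number was not analysed here.

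Splits of the same libraries tell only whether chance can be excluded. It was excluded for L1363P sarcomatoid tumours against adenocarcinomas (4945 calls, as many in 1 of 100 splits, highest other 1286) and against carcinosarcomas (3468, 1 of 100, highest other 2). It was excluded for L1363P adenocarcinomas against KB1P (924, 1 of 100, 360) and KB2P tumours (1683, 1 of 100, 452), for KP adenocarcinomas against KB1P (5045, 1 of 100, 2041) and KB2P tumours (6535, 1 of 100, 1148), for KB1P against KB2P (2439, 1 of 100, 617) and for the 2 KB2P runs (98, 1 of 100, 45). Chance could not be excluded for KB1PM against KB1P titles (164, 17 of 100, highest other 407). Nor could it for L1363P carcinosarcomas against adenocarcinomas (436, 7 of 100, 1918), the difference of this comparison between L1363P and KP mice (2, 28 of 100, 3033) and L1363P against KP adenocarcinomas (34, 23 of 56, 894). In these 3 a split called several times the real count, which points to structure among the tumours other than the labels. The split with 1918 calls set carcinosarcomas 6, 17 and 4 against the other carcinosarcomas and the 3 adenocarcinomas. Where no gene was called every split has as many, so splits say nothing of chance for KP carcinosarcomas against adenocarcinomas (0 calls, 56 of 56 splits, highest other 651) and L1363P against KP carcinosarcomas (0, 100 of 100, 2509).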

How the results depend on the processing

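The alternatives for KB1P run 3528, skeletal muscle libraries, tumours near the sarcomatoid mean, GC content and ribosomal protein genes were chosen only after the results had been seen, and the others before the data were examined. Sarcomatoid tumours against L1363P adenocarcinomas gave 2490 to 4260 calls when 1 adenocarcinoma was left out (4945 otherwise). L1363P carcinosarcomas against adenocarcinomas (436) gave 1119 with the DESeq2 Wald test, 175 with limma on the deposited log2 values, 6 with the compared groups only, 91 without 26.2, 507 without 7.2, 742 without 52, 113 with carcinosarcomas of at least 75% epithelium and 1463 without skeletal muscle libraries. Sarcomatoid tumours against carcinosarcomas (3468) gave 2108 with a log2 fold change of at least 1, 5560 with carcinosarcomas of at least 75% epithelium and 5994 without the tumours of other groups nearest to the sarcomatoid mean (17, 4 and 90.01A). KP carcinosarcomas against adenocarcinomas (0) gave 183 with the DESeq2 Wald test, 1 with limma, 2 with the compared groups only, and 1 or 2 without 130.10A, 5 or 39. The difference of these differences (2) gave 390 with the DESeq2 Wald test, 0 with the compared groups only, with at least 75% epithelium and without 17, 4 and 90.01A, 6 without skeletal muscle libraries, 36, 4 and 11 without 7.2, 26.2 and 52, 116 without 131.03A, 4 without 26.02A, 0 without KP carcinosarcoma 5 and 1 without 89.01A, 90.01A or 39. L1363P against KP adenocarcinomas (34) gave 8 without the count filter, 447 with the DESeq2 Wald test, 17 with limma, 0 with the compared groups only, 364 without skeletal muscle libraries, 2 without 17, 4 and 90.01A, 129, 16 and 61 without 7.2, 26.2 and 52, 283 without 131.03A, 14 without 39, 11 without 90.01A and 7 without 40. L1363P against KP carcinosarcomas (0) gave 2 without the count filter, 6 with the DESeq2 Wald test, 1 without 26.02A and 2 without KP carcinosarcoma 5. L1363P adenocarcinomas against KB1P (924) gave 505 to 567 with 1 adenocarcinoma left out and 178 with KB1P run 3528 only, and against KB2P (1683) 924 with the compared groups only, 863 to 963 with 1 adenocarcinoma left out and 1039 with the GC correction. KP adenocarcinomas against KB1P (5045) gave 3105 to 4865 with 1 KP tumour left out, 3143 with KB1PM run 1756 only and 1471 with KB1P run 3528 only. KB1P against KB2P (2439) gave 1521 with the compared groups only, 953 with a log2 fold change of at least 1, 954 with KB1P titles only, 417 with KB1P run 1857 only, 1583 with KB1PM run 1756 only, 1219 with KB2P run 2749 only and 127 with the tumour number as replicate block in the libraries of shared numbers alone. KB1PM against KB1P titles (164) gave 334 without the count filter, 4 with limma, 2 with the compared groups only, 1 with the replicate block in the 16 libraries of shared numbers alone, 17 without KB1P run 3528 and 87 without ribosomal protein genes and pseudogenes. Both blocked fits thus changed the libraries as well as the model. Tumour numbers shared between the titles did not mark pairs, as 2 of 16 libraries were closest to the library of the same number, and 5 of 16 between KB1P and KB2P. The epithelial slope (1222) gave 2977 with the DESeq2 Wald test, 9 with a log2 fold change of at least 1, 755 without 54.2, 0 with at least 75% epithelium and 2265 without skeletal muscle libraries. The KB2P runs (98) gave 793 with the DESeq2 Wald test, 50 with limma and 62 with a log2 fold change of at least 1. Of 129 set calls 2 held with an estimated correlation, 127 with DESeq2 size factors. The first component held 64.2% with 500 genes and 44.6% with 5000. Of 7 list scores 0 passed without the 2 tumours farthest out. Of 7990 gene values 1263 kept their direction but no longer passed, 14 passed only in the alternative and 57 turned direction. These were Car9 (0.86 without 52, otherwise down to -2.63), Haus7 (-0.076 without 52, otherwise up to 4.597), Krtdap (1.58 without 26.2, otherwise down to -7.223), Rspo2 (-3.79 and -0.29 without 7.2, otherwise up to 6.31 and 9.82), Mzb1 (-1.09 without 90.01A, otherwise up to 2.95), S100a9 (-0.17 without 90.01A, otherwise up to 2.79) and Csn1s2a (-0.76 without 39, otherwise up to 3.29). Without skeletal muscle libraries they were Rspo4 (-1.04), Agtr2 (-0.96), Mybpc1 (-0.66), Acta1 (-0.84), Ckm (-3.61), Des (-0.31 and -0.70), Vwf (-0.19), Xirp2 (-0.012) and Atp2a1 (-1.41). With KB1P run 3528 only they were Rps27 (-0.12), Rpl19 (-0.053), Rps29 (-0.68), Rps13 (-0.80), Rps18 (-0.055 and -0.33), Pgk1 (-0.28), mt-Nd1 (-0.33), Rpl3 (-0.065) and Rpl7 (-0.067). With the GC correction they were Bbc3 (0.034 and 0.007) and Bax (0.62). Between KB1P and KB2P they were Rps6 (-0.60 with KB1PM titles only, -0.60 with run 1756 only, -0.011 with run 1857 only, -0.19 with the replicate block, -0.32 without run 3528), Lor (-0.24 with run 1857 only, -0.44 with the replicate block, -0.43 with the DESeq2 Wald test), Rad51c (-0.066 with the replicate block), and Wnt9b (0.51) and Pcsk2 (1.65) with KB2P run 2459 only. Nefl (0.46) turned with the DESeq2 Wald test between the KB1P titles. For the slope with at least 75% epithelium they were Csn2 (-0.068), Csn1s1 (-0.005), Kit (-0.087), Cspg4 (-0.17), Rgs5 (-0.059), Bard1 (-0.15), Rif1 (-0.069), Fas (0.15), Ccng1 (0.083), Pgk1 (0.073), Birc2 (0.048), Yap1 (0.14), Abcc1 (0.003) and Abcb1b (0.42).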

Other observations

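The levels of Nras and Abcb1b in single tumours were looked up only after the results had been seen, and no test was made of them.

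KP adenocarcinoma 131.03A had 2738 CPM of Nras. Abcb1b lay between 83.6 and 137.5 CPM in the 9 sarcomatoid tumours and at 136.5 CPM in KP adenocarcinoma 90.01A. L1363P carcinosarcomas 17, 4 and 18, the 3 of lowest labelled epithelium, had 101.5, 84.1 and 55.0 CPM. In KB1PM tumours it ran from 35.5 to 291.7 CPM and in KB1P tumours from 1.00 to 15.8. There were 6 libraries that held skeletal muscle genes at 10 or more times the median of the 29 L1363P and KP libraries, among them KP adenocarcinoma 40 and KP carcinosarcoma 130.10A, so muscle genes set some tumours apart from the rest of their group.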
